A study of Danio rerio with 4 samples.

How the data were processed

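Brain tissue of wild-type zebrafish (Danio rerio) was profiled by RNA sequencing in 4 libraries, 1 per group: a vehicle control in 0.1% dimethyl sulfoxide and butylparaben, a preservative ester, at 0.01, 0.1 and 1.0 mg/L. Per the labels' protocols, poly(A) libraries were made with a stranded kit and read as 151 bp paired ends. Whether a library pools several animals, the sex of the fish and the time of day at sampling are not given in the sources used here. The treatment labels name dimethyl sulfoxide for the control only.

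Per the submitters' processing notes, the tools were cutadapt 2.8, STAR 2.7.1a and RSEM 1.3.1, with the genome build GRCz11. The authors deposited 1 table of 32520 genes, which holds for each library an estimated count (expected count), an RPKM value and a TPM value per gene, per the file headers. The deposited counts are whole numbers, and 141 values of 0 counts stand beside an RPKM above 0, so they were taken to be RSEM's expected counts made whole. The same table holds the authors' log2 fold change, p-value and q-value for each dose against the control, per the file headers. The test and scaling behind those p-values are not given in the sources used here. The authors' mark for a changed gene equals a p-value under 0.05 with a log2 fold change of at least 1 in size for all 32520 genes. RSEM shares reads among similar transcripts, so values of close paralogs, such as the egg coat genes and the major histocompatibility genes, are uncertain between members.

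Library totals were 11099317 counts in the control, 10140963 at 0.01 mg/L, 9907714 at 0.1 mg/L and 9750590 at 1.0 mg/L. Of all genes, 7627 had no count in any library. Genes with a mean of at least 1 CPM (counts scaled to a common library size) over the 4 libraries were kept, which left 16522 genes, of which 96.9% were protein coding. Scaling used TMM factors from edgeR 4.0.16 in R 4.3.3, which were 1.01, 0.931, 1.02 and 1.04 in order of dose. Ratios were taken as log2(CPM + 0.5), a scale that understates the ratio of low genes. Folds are ratios of CPM without that addition. Other steps used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

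With 1 library per group no test between conditions could be made, and no p-value is given for any comparison. A gene was called higher or lower when its log2 ratio was at least 1 in size and the exact 95% interval of the ratio (Clopper-Pearson, conditional on the sum of both counts) excluded 1. These intervals, and the floor of 3 counts used for a library at 0, cover counting error only, not the variation between fish. The floor equals 0.267 CPM in the control and 0.318, 0.298 and 0.295 CPM at the rising doses. In simulated data for 1.0 mg/L against control over 16522 genes, the size rule recovered 2.56% of genes changed 1.5-fold, 29.8% of those changed 2-fold, 100% at 3-fold, 97.2% at 4-fold and 97.6% at 8-fold, and it called 32 unchanged genes. These shares rest on 36 to 47 changed genes per fold. The spread between fish is unmeasured here, so the 32 calls give no rate of false calls between real libraries.

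Before the data were examined, 39 gene lists were fixed: pathways of vision, the clock, neurotransmission, memory, stress, detoxification, hormones, immunity and metabolism, and markers of cell types that a dissected brain could hold. A list's median log2 ratio was set against 10000 random lists of the same size, matched on mean expression in 20 bins. It was said to stand apart below percentile 2.5 or above percentile 97.5, for lists with at least 5 measured members. This percentile describes these libraries and is no test of the condition. A further 8 lists, of oocyte, ovary, testis, pineal, retina and clock genes, were chosen after seeing the data.

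The genes named in the text follow a rule fixed in advance. Among genes with a mean of at least 5 CPM that passed the size rule and had an informative symbol, these were the 12 highest and 12 lowest per dose, the 8 highest and 8 lowest over all doses, and the 6 highest and 6 lowest ordered by dose. To them were added the 4 members with the largest ratio of each list that stood apart or concerns light sensing or memory. Genes named outside this rule were chosen after their values were seen, and are said to be so.

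Agreement between doses was compared with 20 simulations of unchanged groups. In one form all 4 libraries were drawn anew around the mean of the libraries, and in the other the real control was kept. Since that mean includes the control, the doses simulated in the second form lie nearer to it than the real ones, and this form excludes nothing. Alternatives planned in advance were size factors from DESeq2 1.42.0, library totals, no filter beyond 1 count, a mean of at least 5 CPM, pseudocounts of 0.1 and 2 CPM, thinning to the smallest library, leaving out mitochondrially encoded genes, and the authors' TPM. The authors' RPKM and 2 ways of leaving out genes high in the control were added after seeing the data. In TPM and RPKM a call rested on the ratio alone, without the counting interval, among genes with a mean of at least 1 in that unit. No coordinates were converted between builds.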

Results

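RNA from the brains of adult zebrafish was sequenced after exposure to butylparaben at 3 concentrations or to 0.1% dimethyl sulfoxide, in a study whose title concerns light sensitivity and memory. Each of the 4 groups held 1 library, so no value below has a replicate, and differences are between libraries. Totals ranged from 9750590 counts at 1.0 mg/L to 11099317 in the control. Mitochondrially encoded genes took 29.3% of counts in the control, 32.3% at 0.01 mg/L, 26.3% at 0.1 mg/L and 28.2% at 1.0 mg/L. Coordinates are those of the authors' table, on GRCz11.

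The widest difference from the control, at every dose, lay in genes of the egg coat. The zona pellucida gene zp2.1 (ENSDARG00000086352, chromosome 20, 54309148 to 54310985) had 1024 counts (91.2 CPM) in the control, 3 counts at 0.01 mg/L, 0 at 0.1 mg/L and 1 at 1.0 mg/L, which at 0.1 mg/L was at least 307-fold lower. The egg coat gene zp3.2 (ENSDARG00000090768) went from 1033 counts in the control to 8, 3 and 0, and zp2.5 from 678 to 0, 4 and 0. All 23 egg coat genes together held 7420 counts in the control and 146, 181 and 139 counts at the rising doses. The linker histone h1m, known from oocytes, had 289 counts in the control and 2, 0 and 1 at the doses, and cldnd, which codes for a claudin of tight junctions, had 239 counts against 2, 1 and 3. Also low were the histone gene h2af1al at 24.1 CPM in the control against 0.099 CPM at 0.1 mg/L, qdprb2 at 20.3 CPM in the control against 0 counts at 0.1 and 1.0 mg/L, and zp3e, zp2.6, zp3a.1 and zpax1. Egg coat genes are best known from the ovary, while the labels name brain as the tissue in all groups.

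**Figure D1:**
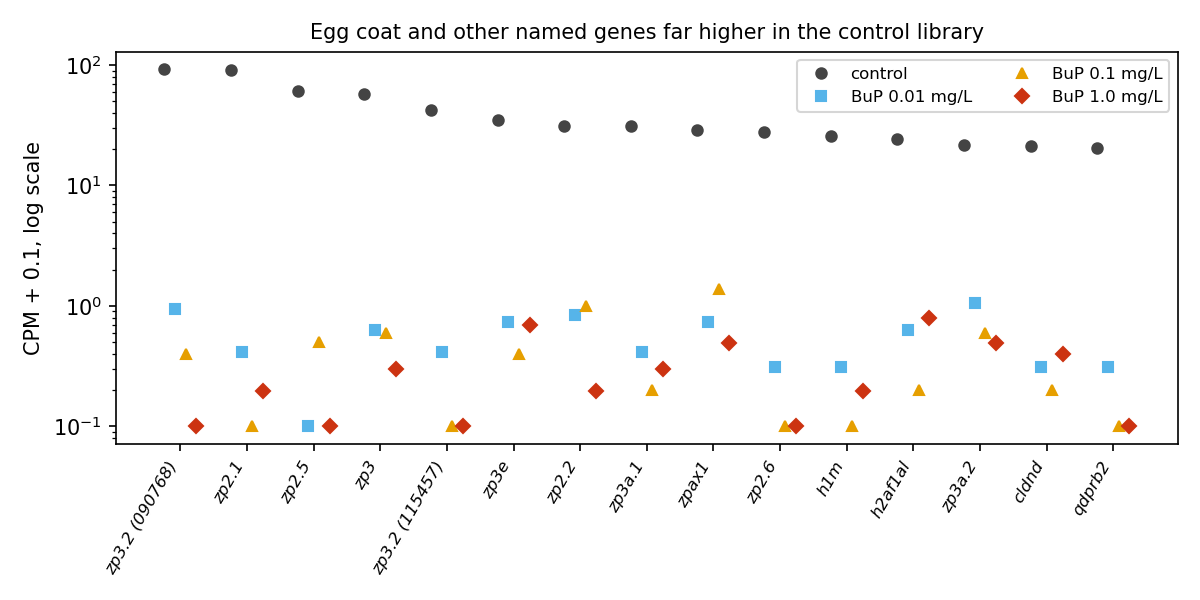
Level of 15 named genes in each library, as CPM + 0.1 on a log axis, with 1 point per gene and library. All lie above 20 CPM in the control (zp3.2 at 92.0 CPM) and under 2 CPM in each of the 3 butylparaben libraries.

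At 0.01 mg/L, 356 of 16522 genes were at least 2-fold higher and 398 at least 2-fold lower than in the control. The prolyl hydroxylase gene p3h3 (ENSDARG00000057879, chromosome 16, 11992498 to 12006828), whose family acts on collagen, was 20.9-fold higher (interval 13.6 to 33.8), at 40.97 CPM against 1.96 CPM. The amino acid transporter gene slc7a2 was 5.83-fold higher, ewsr1b 4.54-fold, the antigen-presentation gene mhc2b 4.16-fold, and rpph1, the RNA of ribonuclease P, 3.84-fold. Other genes in the same group were tgm1l2 (3.57-fold), pla2g3 (3.01-fold), ifi45 (3.204-fold), celsr1a (2.76-fold), myrfl (2.93-fold) and znf1124 (2.71-fold). A second gene with the symbol scg5, on chromosome 19 (ENSDARG00000077045), was 3.96-fold higher. The class I antigen-presentation gene mhc1uba had 478 counts in the control, 1 at 0.01 mg/L, 0 at 0.1 mg/L and 508 at 1.0 mg/L.

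Among the lists, 13 mitochondrially encoded protein genes were all above the control at 0.01 mg/L, with a median log2 ratio of 0.26 above every random list; mt-atp8 had 388 CPM against 172 CPM. The median of endothelial markers stood higher (0.29, percentile 99.99), with 1 of 32 members past the size rule, cldn5b (2.12 CPM against 0.445 CPM). So did that of skin and keratin markers (0.35, percentile 99.99), where 1 of 18 was higher, krt97 (2.65 CPM against 0.713 CPM), and 1 lower. The lower member was epcam, an epithelial adhesion gene also expressed in other epithelia, with 125 counts in the control and 0 at 0.01 mg/L. Inflammatory cytokine and complement genes stood higher (0.25, percentile 99.96, 2 of 36 members), with ccl19a.1 at 6.88 CPM against 3.03 CPM. The visual cycle list was lower (-0.25, percentile 0.21, 3 of 32 members lower and 1 higher); rbp3, which carries retinoids between retinal cells, had 1.80 CPM against 9.09 CPM and lratb.1 had 2.44 CPM against 9.44 CPM. That call was lost under 2 of the 10 alternative settings. Scaling by library totals left 259 genes higher and 506 lower at this dose, so 33.9% of calls were higher where TMM gave 47.2%, with the median gene at -0.12. The authors' TPM gave 267 higher and 586 lower (31.3% higher), and the median gene at -0.19.

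At 0.1 mg/L, 401 genes were higher and 487 lower, and p3h3 (20.2-fold) and several interferon-stimulated genes had the highest ratios among the named genes. The transcription factor gene stat1b (ENSDARG00000076182, chromosome 9, 41218967 to 41247197) was 18.1-fold higher (interval 11.13 to 31.6), at 27.5 CPM against 1.51 CPM, and isg15, a ubiquitin-like protein of the antiviral response, was 11.7-fold higher (interval 8.05 to 17.7). The gene ifi45 was 19.9-fold higher. Of 32 measured members of the interferon list, 13 were at least 2-fold higher and 1 lower (mhc1uba), with a median log2 ratio of 0.58 above every random list. At 0.01 mg/L the same list had a median of 0.07 (percentile 85.6) and at 1.0 mg/L 0.33 (percentile 99.99), where mxc was 6.16-fold and irf1b 2.42-fold higher. Complement c4b (5.94-fold), socs1a, a cytokine-signalling inhibitor (3.72-fold), pla2g3 (4.90-fold), col12a1b (3.93-fold), slc25a23a (3.43-fold), mmp13b (3.13-fold) and slc7a2 (10.6-fold) were among the other named higher genes. So was bin2a (4.87-fold), which was lower at 0.01 and 1.0 mg/L, with 56 counts in the control and 5, 245 and 13 at the rising doses. Of the xenobiotic list, 5 of 35 members were higher at this dose and 1 lower: cyp1a had 39.7 CPM against 16.8 CPM, cyp1d1 8.43 CPM against 2.76 CPM, and ahrra 4.27 CPM against 0.713 CPM. The list as a whole had medians of 0.26, 0.14 and 0.23 at the rising doses (percentiles 99.96, 97.6 and 99.3). Its call held under all 10 alternative settings at 0.01 mg/L and was lost under 5 of them at each of the other doses.

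Ribosomal protein genes were slightly higher at 0.1 mg/L, with 77 of 80 above the control, 0 of them past the size rule, and a median of 0.24 above every random list. At 1.0 mg/L their median was 0.07 (percentile 98.6), a call lost under 2 settings. The median of mitochondrially encoded genes was lower at 0.1 mg/L (-0.14, percentile 0.04), with none past the size rule. The largest change was in mt-nd5 (log2 ratio -0.42), and the next, mt-atp8, went the other way (0.41). The median of microglia and macrophage markers stood above the control at 0.01 and 0.1 mg/L (0.23 and 0.28; percentile 99.96 and above every random list) and not apart at 1.0 mg/L (0.13, percentile 93.6). Its few members past the size rule mostly went the other way, with 1 of 34 higher and 2 lower at 0.01 mg/L and 0 higher and 1 lower at 0.1 mg/L. The cathepsin gene ctss2.1 had 9.09 CPM in the control and 1.27 and 1.19 CPM at these doses, ctsba 61.9 CPM against 21.5 CPM at 0.01 mg/L, and lcp1 29.2 CPM at 0.01 mg/L against 13.8 CPM. At 0.01 mg/L the authors' TPM turned their median to -0.01. Pigment cell markers had a median of 0.44 at 0.1 mg/L, a call lost under 3 settings. Of lower genes outside the egg coat, the neuropeptide gene agrp, which promotes feeding, had 3.57 CPM at 0.1 mg/L against 12.9 CPM, and kiss1 3.57 CPM against 8.91 CPM.

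At 1.0 mg/L, 443 genes were higher and 452 lower, and some genes of photoreceptors and of melatonin synthesis were among the higher ones. The rod transducin gene gnat1 (ENSDARG00000044199, chromosome 6, 42918933 to 42930302) had 117 counts (11.5 CPM) and 4 counts in the control, a 32.3-fold ratio (interval 12.3 to 120). Its partner gngt1 was 14.6-fold higher (interval 8.48 to 27.21), at 18.2 CPM against 1.25 CPM, while the libraries at 0.01 and 0.1 mg/L held 0.741 and 0.198 CPM. The retinol carrier gene rbp4l had 12.7 CPM against 1.69 CPM, the visual cycle gene rpe65a 3.44 CPM against 0.356 CPM, and aanat2, the enzyme that times melatonin synthesis, 5.90 CPM against 1.07 CPM. The gene of the last enzyme of that pathway, asmt, had 3.44 CPM against 0.534 CPM, and exorh, the pineal opsin, 37.4 CPM against 16.1 CPM. Median log2 ratios at 1.0 mg/L were 0.58 in the rod list (percentile 99.8, 3 of 10 higher and 1 lower), 0.53 in the cone list (percentile 99.3, 2 of 8 higher and 0 lower) and 0.36 in the pineal and non-visual photoreception list (percentile 98.7, 3 of 15 higher and 1 lower). The lower members were the guanylate cyclase gene gucy2d, at 2.85 CPM against 6.32 CPM, and still lower at 0.01 and 0.1 mg/L (0.847 and 0.992 CPM), and the opsin gene tmtops2a, at 1.08 CPM against 3.30 CPM. The visual cycle list, which holds rbp4l and rpe65a, did not stand apart at this dose (0.10, percentile 86.3, 5 of 32 higher and 3 lower). The cone call was lost under 2 settings. The pineal call was lost under 2, and its median came to -0.02 with no filter on low values. Rod and pineal genes also differed at 0.1 mg/L, where grk1b (4.46 CPM against 0.445 CPM) and rp1l1a (38.3 CPM against 15.4 CPM) were higher and gngt1 and exorh (6.25 CPM) lower. The rod opsin gene rho, named after its values were seen, with 0 counts at 1.0 mg/L and 5 in the control, was under the filter.

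Neuropeptide genes went both ways. The melanin-concentrating hormone gene pmchl was 3.095-fold higher at 1.0 mg/L (interval 2.89 to 3.32), at 312 CPM against 101 CPM. Oxytocin (oxt) had 140 CPM in the control, 214 CPM at 0.01 mg/L, 64.4 CPM at 0.1 mg/L and 22.1 CPM at 1.0 mg/L, a log2 ratio of -2.63 at the last. The list median was -0.11 at 0.1 mg/L and -0.14 at 1.0 mg/L (percentiles 0.33 and 0.76), each lost under 2 settings. The scg5 gene on chromosome 19 was 17.8-fold higher at 1.0 mg/L, at 14.3 CPM; the gene of that symbol on chromosome 20 (ENSDARG00000032126), named after its values were seen, had 457 CPM against 459 CPM. Also higher were mhc2b (5.58-fold), c4b (5.89-fold), slc7a2 (6.22-fold), ifi45 (3.50-fold), col12a1b (3.31-fold), slc25a23a (3.001-fold) and pla2g3 (3.31-fold). Blood cell markers were lower (-0.31, percentile 0.1), as were skeletal muscle markers (-0.20, percentile 1.34) and, with 6 measured members, the pituitary hormone list (-0.48, percentile 2.26, and -0.60 at 0.1 mg/L). At 1.0 mg/L no member of these lists was called lower, and 1 of the 35 muscle markers was called higher. The blood call was lost with no filter on low values (-0.09), the muscle call under 5 settings, and the pituitary call under 3 at 1.0 mg/L and 4 at 0.1 mg/L. The largest changes in the pituitary list were in pcsk1 and hbegfa, which are not hormone genes (-0.85 and -0.78 at 1.0 mg/L). Of its hormone genes, pomcb was higher and prl2 lower at 1.0 mg/L (0.77 and -0.65). At 0.1 mg/L these 2 went the other way (-0.60 and 0.75), without a call at either dose. Ependymal cilia genes had a median of 0.20 (percentile 98.0), lost under 3 settings.

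**Figure D2:**
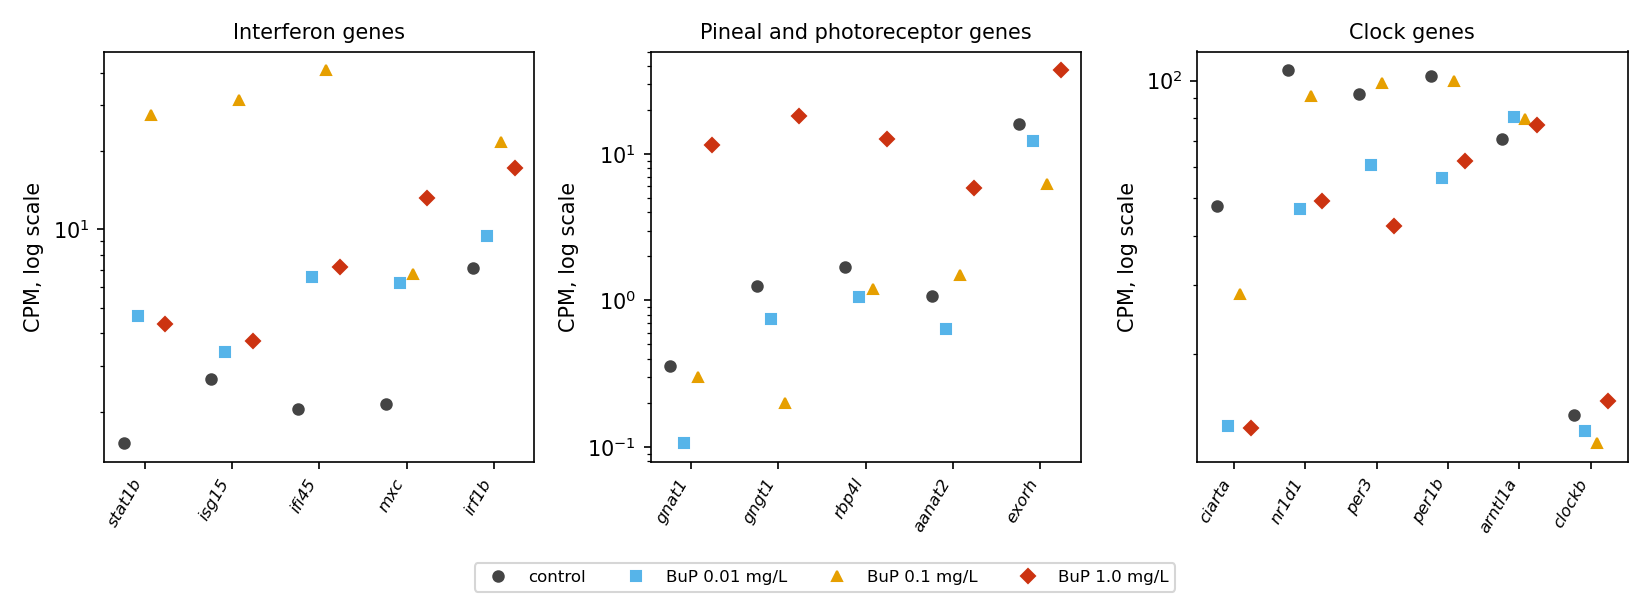
Levels (CPM, log axis) of interferon genes, of pineal and photoreceptor genes and of clock genes, 1 point per library. The library at 0.1 mg/L lies highest for stat1b (27.5 CPM), the library at 1.0 mg/L for gnat1 (11.5 CPM), and ciarta is at 13.02 and 12.9 CPM at 0.01 and 1.0 mg/L against 47.8 CPM in the control.

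The lists of GABA signalling, glutamate signalling and immediate early genes were lower than the control at all 3 doses. GABA signalling had medians of -0.31, -0.47 and -0.50 at the rising doses, each below every random list, with 1, 4 and 5 of 28 measured genes at least 2-fold lower. The GABA synthesis gene gad1a had 5.17 CPM in the control and 2.96, 2.28 and 1.08 CPM at the doses, the GABA transporter gene slc6a1a 44.6 CPM and then 24.7, 19.1 and 17.6 CPM, and the receptor gene gabrz 8.55 CPM against 2.36 CPM at 1.0 mg/L. Glutamate receptors and transport had medians of -0.10, -0.20 and -0.18 (percentile 0.7, below every random list, and percentile 0.15). No member of that list was at least 2-fold lower at any dose, and 1 was higher at 1.0 mg/L, the glial glutamate transporter gene slc1a3b (17.0 CPM against 8.20 CPM). Immediate early genes, which follow neuronal activity, had medians of -0.20, -0.26 and -0.24, with few members passing 2-fold (2, 3 and 0 of 41). Of those passing, egr3 had 21.4 CPM in the control and 9.42 CPM at 0.1 mg/L. Under 2-fold were npas4a, at 334 CPM in the control and 189 CPM at 0.01 mg/L, and egr1, named after its values were seen, at 364 CPM and then 235, 221 and 222 CPM. The median of cholinergic genes was lower at 0.01 mg/L (-0.25, lost under 2 settings) and 1.0 mg/L (-0.45, percentile 0.01), and not apart at 0.1 mg/L (-0.18, percentile 9.25). Past the size rule were only chrnb3a and chrna6 at 0.01 mg/L, and these with chrm3a at 1.0 mg/L, all lower. At 1.0 mg/L chrnb3a had 8.75 CPM against 21.6 CPM. The median of synaptic vesicle genes was lower at 0.01 and 0.1 mg/L (-0.11 and -0.06) and came to -0.10 at 1.0 mg/L (percentile 2.71). Only cplx3b passed the size rule at 0.01 mg/L, and only cplx3b and unc13ba did at 0.1 mg/L, all lower. The median of synaptic plasticity and memory genes was lower at 0.1 and 1.0 mg/L (-0.14 at both, percentiles 0.02 and 0.23), and not apart at 0.01 mg/L (0.01). The call at 1.0 mg/L was lost under 1 setting. The largest change at both doses was in rasgrf2b, at 1.29 and 1.87 CPM against 4.99 CPM, and at 1.0 mg/L it alone passed the size rule. Pan-neuronal markers (0.02, 0.02 and -0.06) and monoamine genes (-0.09, -0.14 and -0.08) did not stand apart at any dose.

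Clock genes were lower at 0.01 and 0.1 mg/L (-0.16 and -0.14; percentiles 0.01 and 0.05) and had -0.09 at 1.0 mg/L (percentile 5.36), with 3, 2 and 5 of 49 members lower and 1 higher at each dose. The clock repressor gene ciarta was at 47.8 CPM in the control and 13.02, 28.5 and 12.9 CPM at the doses, nr1d1 at 106 CPM and then 47.0, 91.3 and 49.3 CPM, and per3 at 92.3 CPM and then 61.0, 98.7 and 42.4 CPM. Heat shock genes were lower at all doses (-0.11, -0.11 and -0.24; percentiles 0.72, 0.42 and below every random list), the call at 0.1 mg/L lost under 2 settings. Of 51 members 0, 3 and 4 were at least 2-fold lower, with hsp70.3 at 6.86 CPM in the control and 3.28, 2.38 and 1.97 CPM at the doses. Astroglia markers were lower at 0.01 and 0.1 mg/L (-0.25 and -0.28, each below every random list) and had -0.12 at 1.0 mg/L (percentile 2.85), with 1 of 33 members lower at 0.01 mg/L, aldoca (104 CPM against 219 CPM), and 0 at the other doses. Proliferation genes were lower (-0.42, -0.29 and -0.30), with 11, 9 and 12 of 45 lower. Among the lowest members were birc5b (56 counts in the control against 2, 0 and 0), ccnb2, and ccnb1 (15.6 CPM in the control against 1.06, 2.18 and 2.07 CPM), the last 2 mitotic cyclins that oocytes also hold in large amounts. With a mean of at least 5 CPM the proliferation call was lost at 0.1 mg/L (-0.01) and the median at 1.0 mg/L came to 0.07; in TPM the call at 1.0 mg/L was lost too (-0.10). Oligodendrocyte markers (0.01, 0.02 and -0.12), oxidative stress genes (0.02, 0.01 and 0.02), oestrogen and androgen genes (0.03, 0.01 and -0.01), thyroid genes (0.05, 0.03 and 0.17), apoptosis genes (0.07, 0.09 and 0.08), cholesterol genes (-0.12, -0.01 and -0.09), lipid genes (0.00, 0.01 and 0.02) and nuclear oxidative phosphorylation genes (0.04, 0.09 and -0.01) did not stand apart. Of the lens crystallin list 3 genes were measured, too few to score. In all, 51 of 114 list comparisons stood apart, 18 higher and 33 lower, where lists of randomly drawn genes would give 5.7. That number takes the genes of a list to vary independently, and the comparisons share 1 control library, so the excess does not measure an effect of dose.

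**Figure D3:**
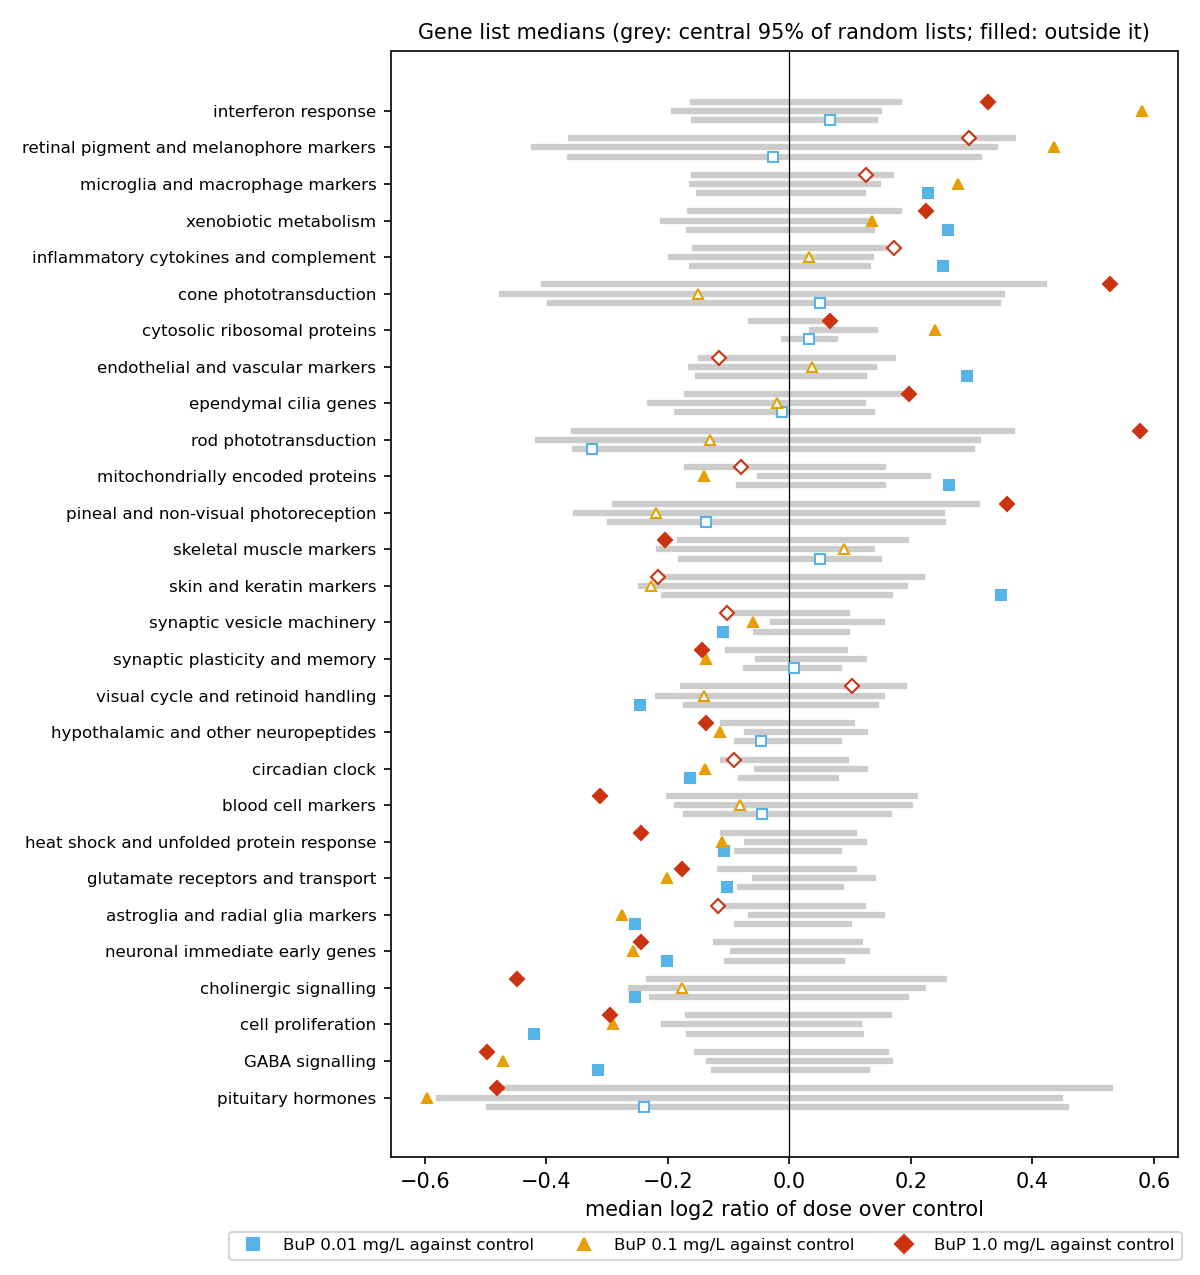
Median log2 ratio of dose over control for the 28 lists that stood apart at 1 dose or more, with the central 95% of matched random lists in grey and filled points outside it. Interferon response reaches 0.58 at 0.1 mg/L and GABA signalling -0.50 at 1.0 mg/L.

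Fewer genes differed between doses than between a dose and the control. Between doses, 554 genes differed at least 2-fold for 0.1 against 0.01 mg/L, 561 for 1.0 against 0.01 mg/L and 538 for 1.0 against 0.1 mg/L, where each dose differed from the control in 754, 888 and 895 genes. This order held under 9 of the 10 alternative settings but not in TPM, where 1.0 against 0.01 mg/L gave 906 genes, more than the 267 higher and 586 lower of 0.01 mg/L against the control. Calls in TPM used no counting interval. The median gene for 1.0 against 0.01 mg/L lay at a log2 ratio of 0.28 in TPM and at 0.02 with TMM. In all 3 doses 101 genes were higher than in the control and 178 lower, and 83 of the 178 had 3 counts or fewer in every dose. Higher at all doses were p3h3, slc7a2, ifi45, pla2g3, mxc, tgm1l2, stat1b and c4b. Lists of independent calls would share 0.232 and 0.321 genes, redrawn libraries gave 0.9 and 0.2, and unchanged doses set against the real control gave 117 and 131. By the same count 44, 50 and 46 genes were higher, and 36, 54 and 38 lower, in the library at 0.01, 0.1 or 1.0 mg/L than in each of the other 3.

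Log2 ratios against the control correlated across genes, which are not independent replicates, with r = 0.72 for 0.01 and 0.1 mg/L, 0.72 for 0.01 and 1.0 mg/L and 0.74 for 0.1 and 1.0 mg/L. Redrawn unchanged libraries gave 0.46, 0.47 and 0.47, since all ratios share the control, and unchanged doses against the real control gave 0.80, 0.80 and 0.81. Pairs that share no library, each dose minus the control against the difference between the remaining doses, gave r of -0.01, 0.09 and 0.10. A shared effect equal at all doses cancels in that difference, so these values cannot show whether the doses share one. An effect shared by the doses and a control library that differs from all of them would both raise the correlations against the control, which do not separate them.

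Ordered by dose, 119 genes had a higher level at each step from control to 1.0 mg/L and 145 a lower one, with a ratio of at least 2 between the ends. The total of 264 ranked 1 of the 12 orders the 4 libraries can take. The next order, with 0.1 and 1.0 mg/L exchanged, gave 255 and also began with the control. Since the control differed from the doses in more genes than they did from each other, orders with the control at an end are favoured whatever the dose. Without genes at 3 counts or fewer in every dose, 250 genes were in order of dose, with the other orders not recounted. With a pseudocount of 2 CPM, after thinning and in TPM the order of dose ranked 2. Besides mxc and pmchl, ordered genes were the calcium channel gene cacna2d4b (25.03, 41.3, 52.7 and 73.6 CPM), arhgef15, map3k7cl and brca2. The first step of pmchl, from 100.7 to 101.1 CPM, lay within counting error. Among those lower at each step foxg1a, a forebrain transcription factor, had 10.2, 6.14, 3.97 and 1.97 CPM. Also lower were gapdh (30.02, 13.3, 11.3 and 9.93 CPM) and jcada (227, 135, 121 and 67 counts). The egg coat genes zp3.2 (8, 3 and 0 counts at the doses), zp3 (5, 5 and 2) and zp3a.2 (9, 5 and 4) were counted too. Their order among the doses rests on few counts.

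The authors' deposited table marked as changed 1289, 1393 and 1396 genes at the rising doses. The p-values and q-values of the authors' deposited table rest on 1 library per group, so neither they nor these marks measure the variation between fish. Of the marked genes, 56.9%, 60.8% and 60.9% at the rising doses passed the size rule used here. The log2 values of the authors' deposited table correlated with those computed here at r = 0.986 for each dose.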

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

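The RPKM setting and the 2 ways of leaving out genes were chosen after seeing the data. Counts of genes moved by over 1.5 times mainly with the filter and the pseudocount, which change by construction which genes can pass. With no filter, higher and lower genes were 581 and 669 at 0.01 mg/L, 613 and 810 at 0.1 mg/L, and 680 and 740 at 1.0 mg/L, with 922, 921 and 913 between doses (0.1 against 0.01, 1.0 against 0.01, 1.0 against 0.1) and 401 ordered by dose. With a mean of at least 5 CPM they were 105 and 87, 137 and 108, and 138 and 121, with 147, 136 and 133 between doses and 86 ordered. A pseudocount of 2 CPM gave 105 and 196, 142 and 221, and 137 and 223, with 174, 166 and 150 between doses and 102 ordered. TPM, where calls used no counting interval, gave 906 for 1.0 against 0.01 mg/L. Of these, 677 were higher and 229 lower, with the median gene at 0.28, and the cause was not tested. Mean agreement between doses, 0.73, came to 0.68 with no filter, 0.75 with a pseudocount of 0.1 CPM and 0.71 with 2 CPM. Of 51 list calls, 31 were lost under none of the 10 settings, where a setting that left a list under 5 measured members was not counted. The calls for mitochondrially encoded genes thus had no value in the setting that leaves those genes out. The list medians that changed sign were pineal genes at 1.0 mg/L (-0.0167 with no filter), proliferation at 1.0 mg/L (0.0677 with at least 5 CPM) and microglia at 0.01 mg/L (-0.0100 in TPM), and the cause was not tested. No called named gene changed sign. Without egg coat genes and the oocyte lists, lower genes numbered 368, 458 and 423, and without genes at 3 counts or fewer in all doses 315, 404 and 369. The first form leaves in genes of a similar profile outside those lists, such as cldnd (239 counts in the control against 2, 1 and 3). It therefore does not measure how many lower genes share the source of the oocyte transcripts. Counting error limits genes near 1 CPM, where about 10 counts stand behind a value, and 1 library per group leaves the spread between fish unmeasured. No paired analysis was possible because each group holds 1 library.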

Other observations

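The tests of scaling, of loss, of pineal tissue and of retina were chosen after the results they measure were seen; those of ovarian follicles and of the daily cycle were written before, although the lower clock repressors themselves had been seen, and the form without nfil3-5 was added after. Markers of testis and sperm, a list chosen after seeing the data, did not stand apart (medians -0.11, 0.03 and 0.16 over 5 measured genes). Of the somatic ovary list, also chosen afterwards, 4 genes were measured, too few to score, and the same held for retina markers, of which 3 were measured. The steroid enzyme gene cyp11a1 had 19 counts in the control and 5, 5 and 3 at the doses, while cyp19a1a had 7, 13, 3 and 3 and gsdf 7, 9, 4 and 7.

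Oocyte transcripts were far higher in the control library than in the 3 butylparaben libraries. All 25 genes of a first set were lower at each dose, but that set was chosen after the data were seen, so this count is no independent evidence. Scaling or depth is argued against, since the median log2 ratio of that set stayed at -4.46 or lower under every scaling tried, after thinning and in TPM and RPKM. RNA of ovarian follicles in the control library may be the source. Of 29 further oocyte markers, however, 14 (48.28%) stood 4-fold or more above the doses, between the limits of 30% and 70% set beforehand. Of the 29, 24 were above the mean of the doses, while 9 exceeded 1 CPM in all dose libraries, so the brain expresses part of the set. This second set was also chosen after seeing the data. Its 14 include the egg coat genes zp3b, zp3c and zp3d.2 and the proliferation gene ccnb1, so it is not independent of the values above. Loss of oocyte transcripts in exposed brains stays open as well. The dose libraries kept a median of 1.03% of the control level of the first set, and its median log2 ratio of 1.0 over 0.01 mg/L was -0.25. A loss complete at the lowest dose thus cannot be told apart from a control library that differs. With 1 control library, every comparison against it carries this difference.

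A part of the photoreceptor and melatonin genes was higher in the 1.0 mg/L library than in the other 3 (gnat1, gngt1, aanat2, asmt and exorh), while gucy2d and tmtops2a lay under the control there, and 3 of 10 rod and 2 of 8 cone genes passed the size rule. Retina or eye tissue as the whole source is argued against, because rho, an abundant rod transcript, had 0 counts there beside 117 of gnat1, an upper bound of 0.032 on their ratio, and the cone opsin genes opn1sw1, opn1sw2 and opn1mw1 had 1 count each. Other retina markers were highest there, among them saga with 18 counts, gnb3b with 12 and opn1lw2 with 5, so a small share of retina stays open. More pineal tissue in that library may account for it, since 16 of 21 pineal markers (76.19%) were highest there, but the test is weak, as 19 of the 21 belonged to lists whose values had been seen, and of the 2 others 1 was highest. A response of pineal genes to the highest dose was not tested and stays open.

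Clock repressors and output genes were lower in the 0.01 and 1.0 mg/L libraries (medians -0.51 and -0.64 over 12 genes) and near the control at 0.1 mg/L (-0.06). These 12 genes were chosen after seeing the data, so their medians are no independent evidence. The clock list fixed in advance stood apart at 0.01 and 0.1 mg/L and not at 1.0 mg/L. Scaling is argued against, since the median stayed at -0.4329 or lower under all scalings tried. Another time of the daily cycle at sampling, which would set activators against repressors, cannot be told apart from other explanations: a list of 7 clock genes meant as activators had medians of 0.03 and 0.12, which lie 0.5441 and 0.7585 above the repressors, but nfil3-5 among them is a repressor, and without it the medians were -0.05 and 0.12, so the opposite sign at 0.01 mg/L was lost. The medians of all 7 lie within the range of random lists (percentiles 64.9 and 78.5). The times of sampling are not given in the sources used here, and an effect of the exposure on the clock stays open.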
